A study of Mus musculus with 6 samples.

How the data were processed

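RNA of bronchoalveolar lavage cells was measured by bulk RNA sequencing in 6 mouse samples, 2 each of the genotypes WT, Cis_KO and Cis_Stat6_DKO. Per the labels, RNA was extracted with Trizol from untreated cells and all samples carry 1 date. The authors deposited, for each sample, a raw count per gene, which per the file headers is a number of reads and was not normalised. The authors also deposited FPKM values, which are counts divided by gene length and by library total, rounded to 0.01. The submitters' processing notes name genome build mm10. The aligner, the counting tool, their versions and the strandedness of the libraries are not given in the sources used here, so counts of overlapping or antisense genes are uncertain, as are those of genes with near-identical paralogs or pseudogenes. Each table held 40564 genes, of which 40415 were found in GENCODE release M21 and 40313 of those shared a start or end coordinate with it.

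Counts were tested with edgeR 4.0.16 in R 4.3.3. The 6 libraries entered 1 fit with the genotype as the factor and no replicate block, after TMM scaling and filterByExpr, which kept 16765 genes. The 3 comparisons between genotypes used the quasi-likelihood F test (glmQLFit, glmQLFTest) with a Benjamini-Hochberg adjusted p under 0.05, two-sided, and standard errors of log2 fold changes were taken as the size of the change over the square root of F. A gene is described as called when it passed this threshold. Normalised read counts (CPM, edgeR's cpm function) used the TMM factors, which ranged from 0.863 to 1.077. For genes with 0 counts in 1 group a lower bound of the fold is given, against 3 counts over the group. For genes with 1 to 3 counts the ratio is given with a 95% interval. Intervals and bounds cover counting error only. The library totals of 50762354 to 65937118 counts compare with a common biological coefficient of variation of 50%, on 3 residual degrees of freedom, so for all but weakly expressed genes the spread between replicates exceeded counting error.

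The comparisons, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined, except where an alternative or test is said to have been added. Some genes that the rule names are not reported here. The rule named Cish and Stat6 in every library and, in Cis_KO against WT and Cis_Stat6_DKO against Cis_KO, the 10 higher and 10 lower called genes with the largest fold change, a mean of at least 5 CPM in the higher group, no overlap between libraries and a symbol that is not a predicted gene, clone or pseudogene. In Cis_Stat6_DKO against WT it named 5 and 5, of the genes moved back the 10 with the largest smaller fold change, and up to 4 members of each list past the set test with the smallest adjusted p, or 2 members of a list not past it. S100a8, S100a9, the genes near Cish and the antioxidant genes and Nfe2l2 that the closing section names were picked for naming after their values were seen, whereas the list of 25 NRF2 targets was set before, and markers of RNA quality were taken from the most abundant genes.

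The 33 gene lists cover macrophage activation states, cell types that lavage fluid can hold and metabolic pathways, and were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Those set tests were repeated with an estimated correlation, and with fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes. Members were also counted with p-values adjusted over the list alone. The lists that passed or are discussed are reported. Enrichment of annotation terms used the terms deposited with the counts and a one-sided hypergeometric test over terms of 10 to 500 tested genes, with annotated tested genes as the background. Genes moved back were those called in Cis_KO against WT and called the other way in Cis_Stat6_DKO against Cis_KO. Their number was compared with 20 simulated sets of unchanged groups and with fits that used a different Cis_KO library in each contrast.

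The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size without scaling, no filter, a filter of at least 1 CPM in 2 libraries, only the groups compared, the replicate number as a block, each library left out, a log2 fold of at least 1, and limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 and with or without a minimum of 0.5 in 2 libraries. Robust empirical Bayes, limma-voom with library quality weights and the removal of 45 abundant ribosomal RNA-like, haemoglobin and mitochondrial genes were added after the data were seen. The test was tried on simulated data with the depths of these libraries, in which a known set of genes was changed. The spread of each gene was the same in all simulated groups, and no simulated library was deviant. The rates that follow may therefore differ from those in the real data. In 15871 genes edgeR called 152, of which 10 had not been changed, and recovered 8% of genes changed 2-fold, 80% of those changed 4-fold and 98% of those changed 16-fold. It called 0 genes in an unchanged comparison, where DESeq2 called 30, and DESeq2 called 247 genes in the changed one, of which 86 had not been changed. Figures were drawn with matplotlib 3.10.9. No sample was left out of the main tests.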

Results

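RNA was sequenced from bronchoalveolar lavage (BALF) cells, the immune cells washed out of the airspaces of the mouse lung, which in an untreated lung are mostly alveolar macrophages. The 6 samples fell into 3 genotypes of 2 replicates each, named WT, Cis_KO and Cis_Stat6_DKO. Cis_KO denotes loss of CIS, the protein of the gene Cish, an SH2-domain inhibitor of cytokine receptor signalling that STAT5 induces. Cis_Stat6_DKO denotes loss of CIS together with STAT6, the transcription factor that carries the signals of interleukin 4 and interleukin 13. No treatment was given, and the labels state a single date for all samples. The read counts summed to 55129216 and 65937118 in WT replicates 1 and 2. They summed to 59414192 and 50762354 in the Cis_KO replicates, and to 65575418 and 52151440 in the Cis_Stat6_DKO replicates. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples only.

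1 library stood apart from the other 5. In Cis_KO replicate 2, haemoglobin genes took 3.29% of the counts, against at most 0.037% in any other library, and 15855 genes had at least 1 count, against 19641 to 20431 elsewhere. The share of counts on CT010467, a gene that collects ribosomal RNA, was 9.77% in this library and 1.38% to 7.87% in the others. The Spearman correlation of log2 expression across genes, which are not independent replicates, was 0.914 to 0.938 between this library and the others and at least 0.957 for every other pair. The first principal component held 50.5% of the variance and separated this library from the rest. Results that rest on it are named where they occur.

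Both targeted genes had lost most of their reads in the mutants. Cish (ENSMUSG00000032578, mm10 chromosome 9, 107296026 to 107302784) stood at 46.2 and 56.2 CPM (read counts scaled to a common library total after TMM normalisation) in the WT libraries, 4.35 and 3.52 in Cis_KO, and 1.72 and 5.04 in Cis_Stat6_DKO. Its log2 fold change was -3.70 ± 0.52 (SE, n = 2 per group) in Cis_KO against WT with an adjusted p of 0.0624 in edgeR, and -3.93 ± 0.52 in Cis_Stat6_DKO against WT with an adjusted p of 0.0767. Neither passed the threshold of 0.05, although the libraries of the mutants did not overlap those of WT. Without Cis_KO replicate 1 the adjusted p of Cish was 0.00476 and 0.0097 in those comparisons, and without Cis_KO replicate 2 it was 0.0389 and 0.00581. With all libraries DESeq2 gave 3.52e-11 and 1.64e-12. Stat6 (ENSMUSG00000002147, mm10 chromosome 10, 127642986 to 127660957) stood at 233 and 227 CPM in WT, 264 and 221 in Cis_KO, and 31.6 and 25.5 in Cis_Stat6_DKO. Stat6 fell by 3.09 ± 0.20 (log2, SE) from Cis_KO to Cis_Stat6_DKO, with an adjusted p of 0.0061, and was 0.08 ± 0.19 apart between Cis_KO and WT, with an adjusted p of 0.87. The files hold a single count per gene, so reads from a remaining part of a targeted gene were not told apart from whole transcripts.

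**Figure D1:**
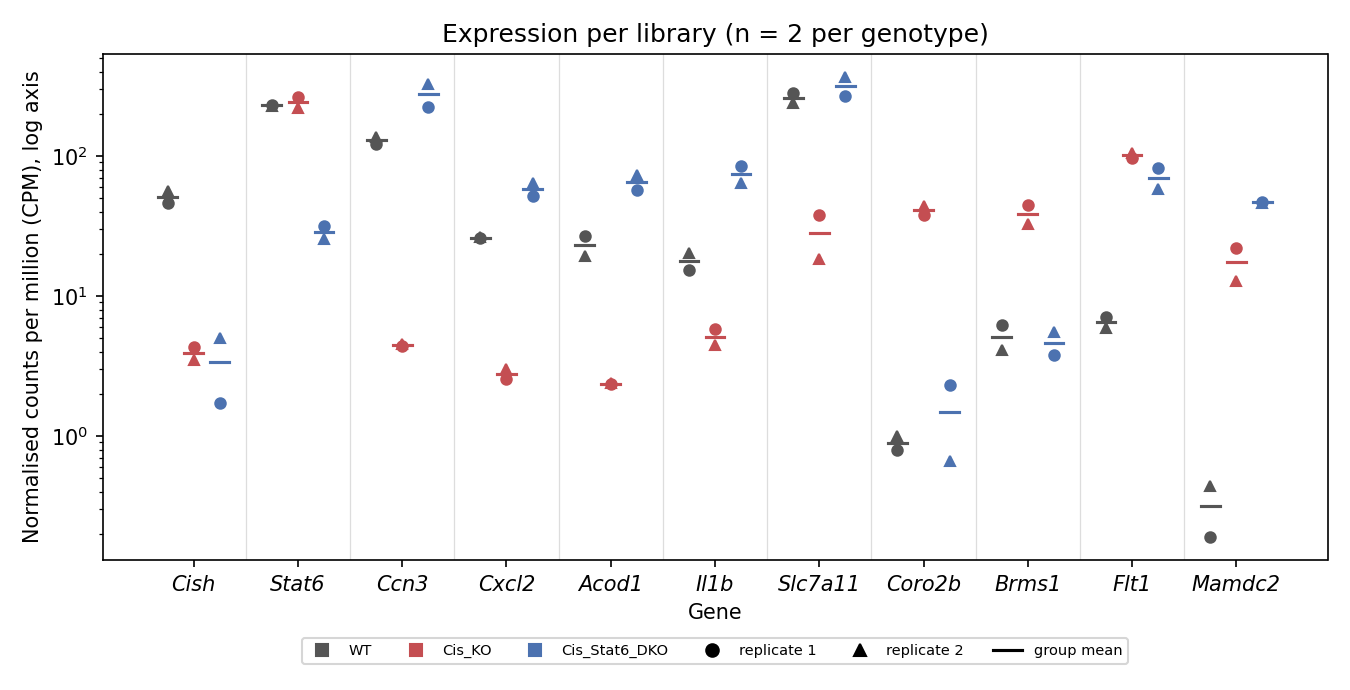
Normalised read counts in CPM (log axis) of 11 genes in each of the 6 libraries, coloured by genotype, with the replicate as the symbol and the group mean as a bar (n = 2 per genotype). Ccn3, Cxcl2, Acod1, Il1b and Slc7a11 lay lowest in both Cis_KO libraries, Coro2b and Brms1 lay highest there, and Flt1 and Mamdc2 lay above WT in both mutant genotypes.

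The comparison of Cis_KO with WT asks what loss of CIS changes in lavage cells. The chemokine gene Cxcl2 and the gene Acod1 were lower without CIS. Cxcl2, a neutrophil-attracting chemokine, stood at 2.78 ± 0.33 CPM (SD, n = 2) in Cis_KO and 26.1 ± 0.187 in WT, and Acod1, which makes the immunometabolite itaconate, stood at 2.36 ± 0.0215 and 23.1 ± 5.29. Ccn3, a secreted matricellular protein (ENSMUSG00000037362, mm10 chromosome 15, 54745702 to 54754039), fell by 4.86 ± 0.26 (log2, SE), from 130.1 ± 10.7 to 4.48 ± 0.0966 CPM, with an adjusted p of 0.00819. Flt1, a receptor for vascular endothelial growth factor (ENSMUSG00000029648, mm10 chromosome 5, 147561604 to 147726011), rose by 3.97 ± 0.26, from 6.46 ± 0.813 to 100.9 ± 5.49 CPM, with the same adjusted p.

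In all, 46 of 16765 tested genes passed the threshold, 20 higher and 26 lower in Cis_KO, and 1862 had an unadjusted p under 0.05, where 838 were to be reached by chance. The balance of directions depended on the method, with 27 higher and 11 lower in limma-voom with library quality weights, 13 and 24 in limma-voom without them, 229 and 309 in DESeq2 and 521 and 500 without a filter. The other genes with the largest falls were the ribosomal protein gene Rpl29 (-5.83 ± 0.61), Plekha6 (-5.22 ± 0.32), the calcium channel subunit Cacna1s (-4.77 ± 0.46), Il1f9, which encodes the cytokine IL-36 gamma (-4.76 ± 0.40), the stress kinase Plk2 (-3.40 ± 0.38), the cystine transporter gene Slc7a11 (-3.20 ± 0.38) and the interleukin 7 receptor gene Il7r (-3.00 ± 0.36). Cxcl2 (-3.23 ± 0.23) and Acod1 (-3.29 ± 0.27) completed this group, and the adjusted p ranged from 0.00819 to 0.0441. Among the genes that rose, Ccbe1, a secreted factor of lymphatic vessel growth, had no counts in WT and was at least 353-fold higher in Cis_KO. Mamdc2 (5.77 ± 0.48), the actin-binding Coro2b (5.51 ± 0.62), the protease inhibitor Spint1 (4.85 ± 0.40), the C-type lectin receptor Clec1b (3.87 ± 0.46), Fam171a1 (3.79 ± 0.48), the lysophospholipid receptor Gpr55 (3.76 ± 0.37), the ribosomal protein gene Rpl30 (3.16 ± 0.37) and the metastasis suppressor Brms1 (2.92 ± 0.35) followed, with adjusted p of 0.0158 to 0.0496. Rpl29 and Rpl30 have processed pseudogenes, and how reads shared with those were assigned is not given in the sources used here. Summed over Rpl30 and its annotated pseudogenes, 7 genes in all, the CPM in Cis_KO against WT differed by 2.09 (log2), less than for Rpl30 alone. That sum differed by 2.03 in Cis_Stat6_DKO against WT. Leaving out either Cis_KO library leaves 1 sample in that group and takes the spread between the pair out of the test. Calls kept in this way are therefore no check of the 46 genes. The number of genes called was 188 without Cis_KO replicate 2 and 5349 without Cis_KO replicate 1, and both sets held 46 of the 46 genes. It was 4 and 3 without WT replicate 1 or 2, and 6 without Cis_Stat6_DKO replicate 1 or 2. Ccn3 and Plekha6 were called whichever single library was left out, and 3 and 2 of the 24 called genes named in this comparison were called without WT replicate 1 or 2.

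A fixed set of 33 gene lists was compared with all other genes in each comparison. Of the 22 measured genes of classical macrophage activation, the response to LPS and interferon gamma, 0 were higher, 2 were lower (Cxcl2 and Acod1) and 20 were not called by edgeR. In the list 10 genes had an unadjusted p under 0.05, and 7 were lower when adjusted over the list alone. The median log2 fold change of this list was -0.96 (camera adjusted p = 6.06e-13), with an adjusted p = 0.528 with an estimated correlation between its genes. Il1b, the gene of interleukin 1 beta, was at -1.80 ± 0.26 with an adjusted p of 0.0707, and Tnfaip3, a feedback inhibitor of NF-kappaB, at -1.11 ± 0.23 with 0.195. Relative to WT, the median of the list was -1.02 in Cis_KO replicate 1 and -1.41 in replicate 2. Of 25 cholesterol synthesis genes, 1 was called lower and 24 were not called, with 6 lower when adjusted over the list alone. Their median was -0.65 (camera adjusted p = 3.65e-05, adjusted p = 0.598 with an estimated correlation). Stard4, which carries sterols between membranes, was at -1.10 ± 0.22 and the HMG-CoA synthase gene Hmgcs1 at -0.79 ± 0.20, with adjusted p of 0.181 and 0.326. The medians per library were -0.30 and -0.93 in the Cis_KO replicates, and the median of the comparison was -0.31 without Cis_KO replicate 2.

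The list of antigen presentation on MHC class II passed camera as higher, without a called member. Of the 11 genes measured, 0 were called over all genes by edgeR, 7 had an unadjusted p under 0.05 and 7 were higher when adjusted over the list alone. Their median was 1.27 (camera adjusted p = 1.74e-07, adjusted p = 0.598 with an estimated correlation). Ciita, their master regulator, was at 2.42 ± 0.51, H2-DMb1 at 0.84 ± 0.19, H2-Ab1 at 1.39 ± 0.35 and the invariant chain gene Cd74 at 1.27 ± 0.33, with adjusted p of 0.204 to 0.344. Without Cis_KO replicate 1, Ciita, H2-DMb1, H2-Ab1 and Cd74 were called, with adjusted p of 0.00713, 0.00367, 0.0228 and 0.0154, and without Cis_KO replicate 2 they were not, with 0.104, 0.13, 0.224 and 0.305. The median of the list was 0.64 without Cis_KO replicate 2. The medians per library were 0.64 and 1.54 in the Cis_KO replicates, against 0.35 and -0.35 in the WT replicates. The WT replicates thus differed from each other by more than Cis_KO replicate 1 did from WT replicate 1. B cells and dendritic cells express MHC class II, and the B cell list was at 4.49 and the dendritic cell list at 1.47 in Cis_KO replicate 2, so a share of such cells in the larger value there was not excluded. The list of 18 dendritic cell genes had a median of 1.00 (camera adjusted p = 0.0131, adjusted p = 0.528 with an estimated correlation). Clec9a was at 4.22 ± 0.98 with an adjusted p of 0.267, and 0 of the 18 were called by edgeR, with 3 at an unadjusted p under 0.05. Its medians per library were 0.18 and 1.47 in the Cis_KO replicates, the median was 0.14 without Cis_KO replicate 2, and the camera adjusted p was 0.0542 without Cis_KO replicate 1. Of 28 interferon-stimulated genes, 0 were called by edgeR and 6 had an unadjusted p under 0.05. Their median was -0.68 (camera adjusted p = 0.00793, adjusted p = 0.645 with an estimated correlation), with Ifit3 at -1.47 ± 0.44 and Ifih1 at -0.79 ± 0.24. The medians were -1.08 in Cis_KO replicate 1 and -0.15 in replicate 2, and the camera adjusted p was 0.907 without Cis_KO replicate 1 (median -0.21) and 0.177 without WT replicate 1 (median -0.28). The median was -1.14 without Cis_KO replicate 2.

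The 27 measured genes that IL-4 and STAT6 induce in macrophages had a median of 0.32 in Cis_KO against WT (camera adjusted p = 0.00609, adjusted p = 0.528 with an estimated correlation). Flt1, which belongs to this list, was called higher and 26 were not called, with 1 higher when adjusted over the list alone. The adhesion molecule gene Cdh1 was at 0.86 ± 0.22 and the chemokine gene Ccl22 at 1.15 ± 0.35. Retnla, a marker of this response, went the other way, with 3 counts in Cis_KO and a value lower by a ratio of 38.7 (95% counting interval 13 to 190), at 1.54 and 0.687 CPM in WT. These 3 genes were not called, with adjusted p of 0.34 to 0.413. The camera adjusted p of this list was 0.226 without Cis_KO replicate 1 (median 0.12) and 0.141 without WT replicate 1 (median 0.17), and the median was 0.21 without Cis_KO replicate 2. The medians per library were 0.24 and 0.18. The 32 alveolar macrophage identity genes had a median of 0.12 (camera adjusted p = 0.194), and 0 were called by edgeR, with 8 at an unadjusted p under 0.05.

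The deviant library set the direction of the erythroid and B cell medians and the call of the oxidative phosphorylation list. The median of 7 erythroid and platelet genes was 6.42 in Cis_KO against WT (camera adjusted p = 0.0269, adjusted p = 0.645 with an estimated correlation) and -3.50 without Cis_KO replicate 2, where the list passed camera as lower (adjusted p 0.00018). The median of 11 B cell and plasma cell genes was 4.81 (camera adjusted p = 0.0452, adjusted p = 0.663 with an estimated correlation) and -0.81 without that library (camera adjusted p 0.411). The median of 37 oxidative phosphorylation genes was 0.46 (camera adjusted p = 3.65e-05, adjusted p = 0.645 with an estimated correlation) and 0.04 without it, with a camera adjusted p of 0.389. The 5 sex-linked genes had a median of -0.83 (camera adjusted p = 0.0358, adjusted p = 0.598 with an estimated correlation), and a camera adjusted p of 0.0732 without that library (median -0.37) and 0.0622 without WT replicate 2. The sex-linked median was -1.53 without Cis_KO replicate 1, and the oxidative phosphorylation median 0.78. The sex-linked list mixes genes of the X and Y chromosomes, so its direction cannot be read as a difference of sex. Over all libraries Xist stood at no more than 1.11 CPM and the Y-linked Ddx3y at 17.9 to 68.2 CPM. These genes gave no sign that the genotypes differed in sex. The 32 proliferation genes had a median of 0.21 (camera adjusted p = 0.0269, adjusted p = 0.598 with an estimated correlation), with the replication genes Mcm5 at 0.70 ± 0.17 and Mcm6 at 0.73 ± 0.17. The proliferation list did not rest on the deviant library, without which its median was 0.19 and its camera adjusted p 0.00114. Its camera adjusted p was 0.288 without Cis_KO replicate 1 and 0.0799 without WT replicate 2 (median 0.12). By edgeR, 0 members of these 5 lists were called, and 3, 3, 2, 0 and 8 of them, in this order, had an unadjusted p under 0.05.

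**Figure D2:**
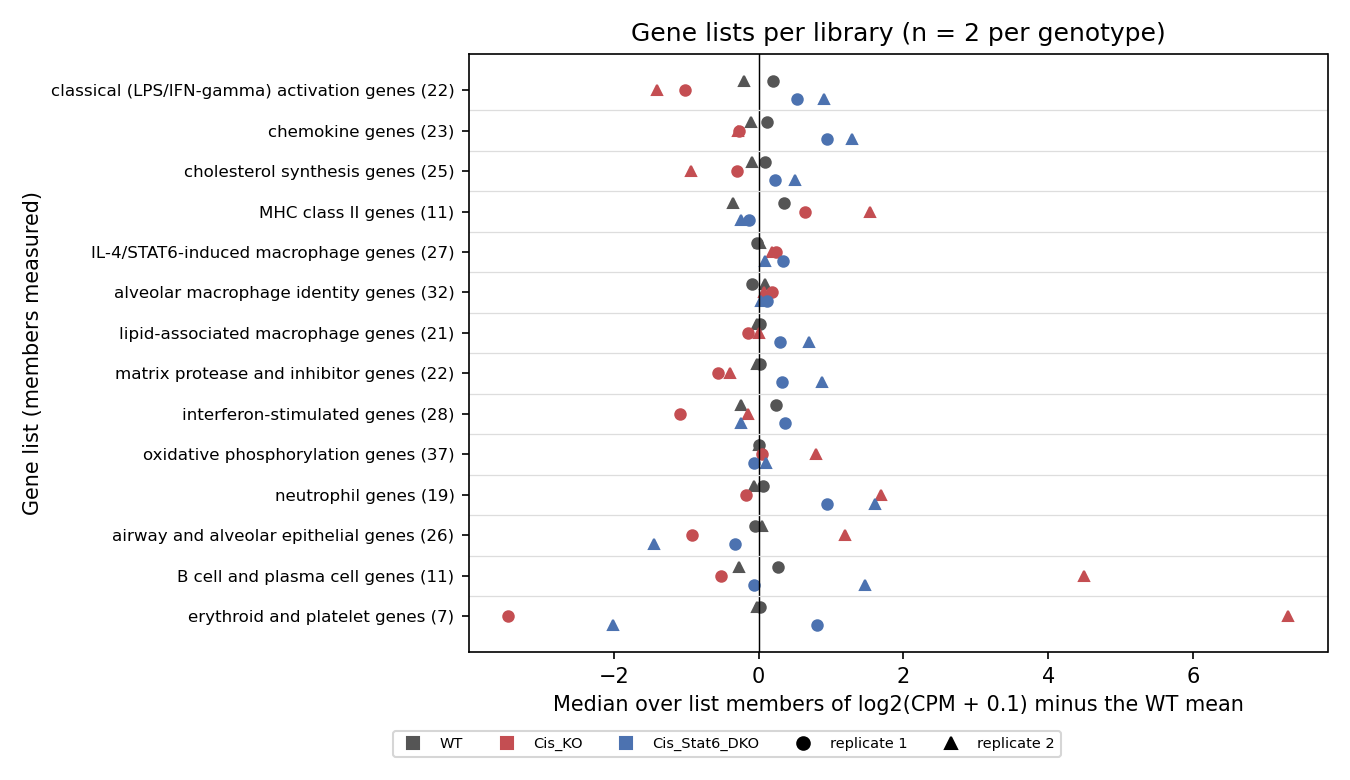
Median over list members of log2(CPM + 0.1) minus the WT mean, for 14 gene lists in each of the 6 libraries, with the number of members measured in parentheses, the genotype as colour and the replicate as symbol. Classical activation genes lay at -1.02 and -1.41 in the Cis_KO libraries and at 0.53 and 0.90 in the Cis_Stat6_DKO libraries, while the erythroid list reached 7.32 in Cis_KO replicate 2 alone.

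The comparison of Cis_Stat6_DKO with Cis_KO asks what loss of STAT6 adds in cells without CIS. The inflammatory genes Cxcl2, Acod1 and Il1b were higher when STAT6 was also lost. Cxcl2 rose by 4.38 ± 0.24 (log2, SE, n = 2 per group), from 2.78 ± 0.33 to 57.8 ± 8.57 CPM, Acod1 by 4.78 ± 0.28 to 64.8 ± 11.2 CPM, and Il1b by 3.86 ± 0.28, with adjusted p of 0.00374, 0.0047 and 0.00937. Ccn3 rose by 5.95 ± 0.28, from 4.48 ± 0.0966 to 276.9 ± 73.8 CPM, with an adjusted p of 0.0037. Cers4, a ceramide synthase, fell by 7.16 ± 0.38 (adjusted p 0.00374) and Hal, which breaks down histidine, by 7.04 ± 0.53 (adjusted p 0.00937).

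In this comparison 60 genes were called, 40 higher and 20 lower in Cis_Stat6_DKO, and 3064 had an unadjusted p under 0.05. This balance depended on the method as well, with 9 higher and 14 lower in limma-voom with quality weights, 46 and 16 in limma-voom without them, 773 and 766 in DESeq2 and 969 and 871 without a filter. Skint3 had no counts in Cis_KO and was at least 537-fold higher in Cis_Stat6_DKO. Ear6 (9.30 ± 1.23) and Rnase2b (7.80 ± 0.92) rose; both are eosinophil-type ribonucleases of a family of near-identical genes, so which member the reads came from is uncertain. Gdpd3 (6.26 ± 0.82), the neutrophil chemokine Cxcl3 (5.49 ± 0.59), the matrix glycoprotein Thbs1 (5.09 ± 0.57), Cacna1s (5.05 ± 0.46) and Il1f9 (4.96 ± 0.40) rose as well. The adjusted p of these genes was 0.012 to 0.0492. Ear6 stood at 49.6 and 218 CPM in the Cis_Stat6_DKO replicates. Among genes that fell, the sulfotransferase gene Sult2b1 and the sialyltransferase gene St6galnac1 had no counts in Cis_Stat6_DKO and were at least 1020-fold and 265-fold lower. BC018473 had 3 counts there and was lower by a ratio of 2730 (95% counting interval 935 to 13300). The plexin gene Plxnb2 (-6.13 ± 0.47), Coro2b (-4.77 ± 0.59), Fam171a1 (-3.69 ± 0.48) and Brms1 (-3.06 ± 0.35) fell as well, as did Stat6 itself. Leaving out either Cis_KO library again takes the spread between the pair out of the test, so calls kept there are no check of the 60 genes. The number of genes called was 495 without Cis_KO replicate 2 and 5999 without Cis_KO replicate 1, and both sets held 60 of the 60 genes. It was 37 and 29 without WT replicate 1 or 2, and 11 and 4 without Cis_Stat6_DKO replicate 1 or 2. Ccn3, Cxcl2, Plekha6 and BC018473 were called without either Cis_Stat6_DKO library, among 8 and 4 of the 27 called genes named here.

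Among classical activation genes, 3 of 22 were called higher (Cxcl2, Acod1 and Il1b), 0 lower and 19 were not called, with 13 higher when adjusted over the list alone. The median was 1.68 (camera adjusted p = 2.63e-21, adjusted p = 0.358 with an estimated correlation). Il1a was at 2.33 ± 0.34 with an adjusted p of 0.0641. The 19 neutrophil genes did not pass in this comparison (median -0.41, camera adjusted p = 0.118). When adjusted over the list alone, 6 of them were higher and 1 was lower. A share of neutrophils in the rise of activation genes was therefore not excluded. Of 23 chemokine genes, Cxcl2 and Cxcl3 were called higher and 21 were not called, with 6 higher and 1 lower when adjusted over the list alone. The median was 1.23 (camera adjusted p = 8.09e-06, adjusted p = 0.358 with an estimated correlation). Ccl3 was at 3.15 ± 0.69 and Cx3cl1 at -1.67 ± 0.35. Cholesterol synthesis genes had a median of 1.03 (camera adjusted p = 3.67e-10, adjusted p = 0.538 with an estimated correlation). Of these 25 genes 1 was called higher and 24 were not called, with 15 higher when adjusted over the list alone. Stard4 was at 1.40 ± 0.22 and Hmgcs1 at 1.15 ± 0.20. MHC class II genes had a median of -1.60 (camera adjusted p = 6.75e-08, adjusted p = 0.542 with an estimated correlation). By edgeR 0 of 11 were called, with 8 at an unadjusted p under 0.05 and 8 lower when adjusted over the list alone. Cd74 was at -1.98 ± 0.34, H2-DMb1 at -1.02 ± 0.19 and H2-Ab1 at -1.60 ± 0.35. The camera adjusted p of the chemokine list was 0.0761 without Cis_KO replicate 1, and its median was 0.74 without Cis_Stat6_DKO replicate 2. The MHC class II median was -1.06 without Cis_KO replicate 2, and the activation median 2.74 without Cis_KO replicate 1. The camera adjusted p of the activation, cholesterol and MHC class II lists stayed under 0.05 whichever single library was left out.

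Of 22 matrix protease and inhibitor genes, the cathepsin gene Ctsk (2.28 ± 0.25) and the membrane metalloprotease gene Mmp14 (3.66 ± 0.41) were called higher, both with an adjusted p of 0.0313, and 20 were not called, with 7 higher and 1 lower when adjusted over the list alone. Their median was 0.57 (camera adjusted p = 7.25e-05, adjusted p = 0.402 with an estimated correlation), and the urokinase gene Plau was at 2.63 ± 0.35 with an adjusted p of 0.0521. Of 21 lipid-associated macrophage genes, Mmp14 was called higher and 20 were not called, with 10 higher and 1 lower when adjusted over the list alone. The median was 0.64 (camera adjusted p = 4.93e-05, adjusted p = 0.581 with an estimated correlation). The elastase gene Mmp12 was at 2.69 ± 0.47, Gpnmb at 0.91 ± 0.21 and the osteopontin gene Spp1 at 1.38 ± 0.32. Without Cis_KO replicate 1 the camera adjusted p was 0.182 for the protease list and 0.107 for the lipid-associated list, and without Cis_KO replicate 2 the median of the protease list was 1.11.

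The IL-4 and STAT6-induced list did not pass in this comparison. Its median was -0.10 (camera adjusted p = 0.631), 0 of 27 genes were called by edgeR, and 1 was lower when adjusted over the list alone. The prostaglandin synthase gene Ptgs1 was at -1.99 ± 0.35 with an adjusted p of 0.0925, and the chitinase-like gene Chil3 at 1.53 ± 0.39 with 0.163, at 11600 and 6880 CPM in Cis_KO against 22300 and 31100 in Cis_Stat6_DKO. The alveolar macrophage identity list did not pass either (median 0.06, camera adjusted p = 0.987), but its members moved both ways. Ctsk was called higher and 31 of 32 were not called, 19 had an unadjusted p under 0.05, and 8 were higher and 7 lower when adjusted over the list alone. Krt19 was at -1.34 ± 0.27 with an adjusted p of 0.116. Interferon-stimulated genes had a median of 0.62 (camera adjusted p = 0.025, adjusted p = 0.667 with an estimated correlation), with Ifih1 at 1.03 ± 0.24 and Ifit3 at 1.59 ± 0.44. The camera adjusted p of that list was 0.831 without Cis_KO replicate 1 (median 0.16) and 0.338 without Cis_Stat6_DKO replicate 1 (median 0.20), and its median was 1.09 without Cis_KO replicate 2. The 26 airway and alveolar epithelial genes had a median of -1.62 (camera adjusted p = 0.00207, adjusted p = 0.667 with an estimated correlation), with the surfactant gene Sftpb at -3.62 ± 0.84 and Tppp3 at -2.13 ± 0.52. The epithelial medians relative to WT were -0.92 and 1.19 in the Cis_KO replicates, and the camera adjusted p was 0.544 without Cis_KO replicate 2 (median -0.10) and 0.094 without Cis_Stat6_DKO replicate 2. Oxidative phosphorylation genes (median -0.46, camera adjusted p = 0.000903, adjusted p = 0.667 with an estimated correlation) and sex-linked genes (0.87, camera adjusted p = 0.0409, adjusted p = 0.664 with an estimated correlation) were at a camera adjusted p of 0.588 and 0.104 without Cis_KO replicate 2, with medians of -0.01 and 0.33, against -0.78 and 1.83 without Cis_KO replicate 1. The erythroid and platelet median of -6.43 (camera adjusted p = 0.0181, adjusted p = 0.667 with an estimated correlation) turned to 3.50 without Cis_KO replicate 2, where the list passed camera in the other direction (adjusted p 0.0111).

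Terms of the gene annotation deposited with the counts were tested for enrichment among called genes. Genes higher in Cis_Stat6_DKO than in Cis_KO were enriched for immune response (7 genes, adjusted p 0.00129), inflammatory response (6 genes, 0.0494), ribonuclease activity (3 genes, 0.0407) and RNA phosphodiester bond hydrolysis (3 genes, 0.0494), out of 3236 terms of 10 to 500 genes among 11873 annotated genes. Ribonuclease activity and RNA phosphodiester bond hydrolysis rest on the same genes, Ear6, Rnase2b and Rnase6. Immune response and inflammatory response share Cxcl2, Cxcl3, Il1b, Il1f9 and Thbs1. The terms are thus not independent of each other. No other set of called genes had a term past the threshold. Without Cis_Stat6_DKO replicate 1 or 2 the number of terms was 0, and it was 165 without Cis_KO replicate 1 and 80 without Cis_KO replicate 2, and 9 and 11 without WT replicate 1 or 2. Of the 4 terms, 0 were among the 165, 4 among the 80, and 2 each among the 9 and the 11. With limma-voom 1 term passed, which was none of the 4.

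Changes with CIS loss were then followed into the double mutant. No genotype lacked STAT6 alone, so a dependence of these changes on STAT6 and a separate effect of STAT6 loss cannot be told apart. Of the 46 genes called in Cis_KO against WT, 25 were called in the opposite direction in Cis_Stat6_DKO against Cis_KO, and 0 were called further in the same direction. Of the 26 genes that fell in Cis_KO, 19 rose again, and the median share of the change that was undone was 1.03. Of the 20 genes that rose in Cis_KO, 6 fell again, with a median share of 0.14. Ccn3, Cacna1s, Il1f9, Plekha6, Plk2, Acod1, Cxcl2 and Slc7a11 fell and rose again, and Coro2b and Fam171a1 rose and fell again. Against WT, the double mutant was then at 1.09 ± 0.22 for Ccn3, 1.49 ± 0.24 for Acod1, 1.15 ± 0.21 for Cxcl2, 0.05 ± 0.34 for Plk2, 0.29 ± 0.35 for Slc7a11, 0.20 ± 0.33 for Il1f9 and -1.12 ± 0.27 for Plekha6 (log2, SE). These 7 genes were not called in that comparison by edgeR. Without Cis_KO replicate 1 or 2, Ccn3 (adjusted p 0.0434 and 0.0342), Acod1 (0.0179 and 0.013) and Cxcl2 (0.0166 and 0.0127) were called above WT. Both contrasts share the Cis_KO libraries, which alone favours opposite signs and draws the share undone towards 1. In 20 simulated sets of unchanged groups 0.15 genes on average and at most 1 gene moved back. The draws gave every group the same spread, so they may understate the number that arises by chance here. Library quality weights were 0.33 and 0.34 for the Cis_KO libraries against 1.34 to 2.27 for the others. With 2 libraries per group such weights reflect the spread of the group and cannot tell its libraries apart. Over all genes, the fold changes of both contrasts correlated at -0.7, against a simulated mean of -0.51. With the Cis_KO libraries split, 1 in each contrast, this correlation was only -0.16 and -0.14. Of the 46 genes, which had been selected with both libraries, 39 and 35 then had opposite signs. In these fits 75 of 114 and 184 of 5337 genes called in Cis_KO against WT were called as moved back. The count of 25 was 113 without Cis_KO replicate 2, 4549 without Cis_KO replicate 1, 2 without WT replicate 1 or WT replicate 2, and 4 and 2 without Cis_Stat6_DKO replicate 1 or 2.

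The comparison of Cis_Stat6_DKO with WT shows what differs when both genes are lost. Mamdc2 (7.18 ± 0.51), Gpr55 (4.61 ± 0.38), Spint1 (4.00 ± 0.39) and Flt1 (3.43 ± 0.25) rose (log2, SE, n = 2 per group, adjusted p of 0.00988 to 0.0284), and Ccbe1 and Skint3, with no counts in WT, were at least 649-fold and 630-fold higher. Hal (-7.60 ± 0.54), Cers4 (-5.70 ± 0.36), Rpl29 (-5.65 ± 0.60) and Stat6 (-3.01 ± 0.20) fell, with adjusted p of 0.00988 to 0.042. Clca1, a secreted protein of mucus-producing epithelium, had 3 counts in Cis_Stat6_DKO and was lower by a ratio of 525 (95% counting interval 179 to 2550), and BC018473 by a ratio of 246 (84.0 to 1200). In all 22 genes were called, 11 higher and 11 lower, and 898 had an unadjusted p under 0.05, where 838 were to be reached by chance. With only the WT and Cis_Stat6_DKO libraries in the edgeR fit, 277 of 16182 genes were called and 2305 had an unadjusted p under 0.05. That fit leaves out the spread of the Cis_KO libraries. Mamdc2, Ccbe1, Gpr55, Spint1, Flt1 and Rpl29 were among 9 genes called in the same direction in both mutants against WT. In simulated unchanged groups that shared the WT libraries and had equal spread, at most 2 genes were shared in this way. Over all genes, however, the fold changes of both mutants against WT correlated at 0.32, below the simulated mean of 0.5. Their covariance was 0.661, against a simulated 0.555 ± 0.023 (SD). The number called was 350 without Cis_KO replicate 2 and 307 without Cis_KO replicate 1, which enter this comparison only through the estimate of the spread and the filter. It was 9 and 5 without WT replicate 1 or 2. In edgeR it was 0 without Cis_Stat6_DKO replicate 1 or 2, with 802 and 397 genes then at an unadjusted p under 0.05. With all libraries DESeq2 called 317 and limma-voom 26.

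The classical activation, chemokine and neutrophil lists passed camera above WT in the double mutant, and did not pass with an estimated correlation. Classical activation genes had a median of 0.90 (camera adjusted p = 5.41e-08, adjusted p = 0.379 with an estimated correlation). By edgeR 0 of 22 were called, with 8 at an unadjusted p under 0.05 and 6 higher when adjusted over the list alone. Il1b was at 2.06 ± 0.26 with an adjusted p of 0.069, and at 0.0053 and 0.00347 without Cis_KO replicate 1 or 2. Chemokine genes had a median of 0.94 (camera adjusted p = 2.02e-06, adjusted p = 0.362 with an estimated correlation). Of these 0 of 23 were called, with 9 at an unadjusted p under 0.05 and 6 higher when adjusted over the list alone, and Ccl6 was at 1.32 ± 0.27. The 19 neutrophil genes had a median of 1.63 (camera adjusted p = 3.62e-07, adjusted p = 0.379 with an estimated correlation). Of these 0 were called, with 8 at an unadjusted p under 0.05 and 3 higher and 1 lower when adjusted over the list alone. The chemokine receptor gene Cxcr2 was at 1.63 ± 0.35, the histamine-forming Hdc at 3.39 ± 0.82 and the G-CSF receptor gene Csf3r at -0.95 ± 0.18. Relative to WT the neutrophil medians were 0.95 and 1.61 in the Cis_Stat6_DKO replicates, and -0.17 and 1.69 in the Cis_KO replicates. Without Cis_Stat6_DKO replicate 2 the medians of the comparison were 0.59 for the activation list and 0.78 for the neutrophil list. The neutrophil gene S100a9 stood at 1.35 and 1.24 CPM in WT, 0.438 and 133 in Cis_KO, and 27.7 and 72.3 in Cis_Stat6_DKO.

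Lipid-associated macrophage genes had a median of 0.46 against WT (camera adjusted p = 2.35e-07, adjusted p = 0.379 with an estimated correlation), with the tetraspanin gene Cd63 at 1.67 ± 0.33, the growth factor gene Igf1 at 1.22 ± 0.30 (adjusted p of 0.227 and 0.4). By edgeR 0 of 21 were called, with 9 at an unadjusted p under 0.05 and 4 higher when adjusted over the list alone. Matrix protease genes had a median of 0.81 (camera adjusted p = 2.64e-05, adjusted p = 0.362 with an estimated correlation), with Ctsk at 1.71 ± 0.25 and Plau at 1.52 ± 0.34 (adjusted p of 0.0979 and 0.329). Of these 0 of 22 were called by edgeR, with 6 at an unadjusted p under 0.05 and 3 higher when adjusted over the list alone. The 25 cholesterol synthesis genes had a median of 0.34 (camera adjusted p = 0.000166, adjusted p = 0.457 with an estimated correlation), with Acat2 at 0.63 ± 0.27 and Fdps at 0.56 ± 0.25. The 40 lysosomal genes had a median of 0.20 (camera adjusted p = 0.00243, adjusted p = 0.429 with an estimated correlation), with Glb1 at -0.75 ± 0.20 and Atp6v0d2 at 0.64 ± 0.20. In the cholesterol and lysosomal lists edgeR called 0 members, also when adjusted over the list alone, with 0 and 4 at an unadjusted p under 0.05. Of 26 glycolysis and hypoxia genes, Car9, a hypoxia-induced carbonic anhydrase, was at 5.04 ± 0.59 with an adjusted p of 0.0512 and the only one called over the list alone, and Hk2 was at 0.77 ± 0.29. Their median was 0.16 (camera adjusted p = 0.0388, adjusted p = 0.393 with an estimated correlation), and the camera adjusted p was 0.282 without WT replicate 2 and 0.156 without Cis_Stat6_DKO replicate 2 (median 0.10). Ndrg1 of that list went the other way, at -0.77 ± 0.39. Without Cis_Stat6_DKO replicate 2 the medians fell to 0.30 for the matrix protease list, 0.29 for the lipid-associated list, 0.22 for the cholesterol list and 0.12 for the lysosomal list. The IL-4 and STAT6-induced list stood above WT although STAT6 was lost, with a median of 0.26 (camera adjusted p = 0.00298, adjusted p = 0.362 with an estimated correlation), Flt1 called, and 3 higher and 1 lower when adjusted over the list alone. Its members Ch25h, Cdh1 and Ptgs1 were at 1.64 ± 0.31, 0.99 ± 0.22 and -1.98 ± 0.35. Its camera adjusted p was 0.333 and 0.112 without Cis_KO replicate 1 or 2, 0.0926 without WT replicate 1 and 0.145 without Cis_Stat6_DKO replicate 1, where the median was -0.03. Epithelial genes had a median of -0.93 (camera adjusted p = 0.000112, adjusted p = 0.69 with an estimated correlation), with Epcam at -2.28 ± 0.45 and Cyp2f2 at -1.79 ± 0.65, and a camera adjusted p of 0.103 (median -0.53) without Cis_Stat6_DKO replicate 2. Without Cis_Stat6_DKO replicate 1 the epithelial median was -1.57. The fall of Epcam was not particular to the double mutant. It stood at 28.9 and 22.6 CPM in WT, 3.36 and 4.41 in Cis_KO, and 7.46 and 3.15 in Cis_Stat6_DKO. In Cis_KO replicate 2 the median of the epithelial list was nevertheless 1.19 above WT.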

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

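Robust empirical Bayes, limma-voom with library quality weights and the removal of abundant genes were chosen after seeing the data, and the other alternatives were planned. Counts are given in the order Cis_KO against WT, Cis_Stat6_DKO against Cis_KO, Cis_Stat6_DKO against WT, and genes moved back, followed by annotation terms, and were 46, 60, 22, 25 and 4 as reported. They stayed within 1.5 times of these with limma-voom (37, 62, 26, 23), RLE factors (47, 60, 22, 26), at least 1 CPM in 2 libraries (53, 65, 23, 29), robust empirical Bayes (46, 67, 26, 27) and abundant genes left out (47, 65, 26, 27), and a log2 fold of at least 1 removed no gene. The limma-voom calls held 28 of 46, 43 of 60, 12 of 22 and 17 of 25 reported genes. Terms were 1 with limma-voom and 8 with the CPM filter. Of the 4 reported terms, 4 were found with RLE factors, the CPM filter and FPKM with a pseudocount of 0.1. Of them 2 each were found with robust empirical Bayes, abundant genes left out, DESeq2, library size only, the replicate block and FPKM with a pseudocount of 1, 1 each without a filter and with quality weights, and 0 with limma-voom, with only the groups compared and with FPKM without a filter. DESeq2 called 538, 1539, 317 and 314 with 119 terms, and no filter gave 1021, 1840, 385, 730 and 176, both including 46 of 46, 60 of 60, 22 of 22 and 25 of 25 reported genes. Library size without scaling gave 26, 29, 20, 12 and 15. FPKM with a pseudocount of 1 gave 74, 191, 52, 39 and 41, with a pseudocount of 0.1 it gave 59, 99, 35, 35 and 39, and without a filter 2, 2, 1, 1 and 0. Of the genes called, 20 of 46 and 40 of 60 were higher as reported in the first comparisons, against 229 of 538 and 773 of 1539 with DESeq2 and 521 of 1021 and 969 of 1840 without a filter. Quality weights gave 38, 23, 470, 10 and 43, with 27 of 38 and 9 of 23 higher, and weights of 0.33 and 0.34 for the Cis_KO libraries against 1.34 to 2.27 for the others. The cause of these shifts was not tested, and with 2 libraries per group the weights reflect a group's spread rather than 1 library's quality.

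With only the groups compared, and so fewer samples, the counts were 6, 5, 277, 1 and 10. The Cis_KO libraries, which hold the deviant replicate, take no part in the count of 277. With the replicate number as a block the counts were 24, 28, 12, 11 and 14. Differences between replicates 1 and 2 correlated between genotypes at -0.03, -0.07 and 0.01, so no effect shared by samples of the same number was seen. The labels do not say whether such samples were paired, and the Cis_KO difference holds the deviant replicate. Using a different Cis_KO library in each contrast gave 75 and 184 genes moved back. Leaving out 1 library, where the lone sample of a group is assumed to vary like the others, gave 3 to 5349, 4 to 5999, 0 to 350, 2 to 4549 and 0 to 165. The highest came without a Cis_KO library and the lowest without a WT or Cis_Stat6_DKO library. Where edgeR called 0 in Cis_Stat6_DKO against WT, without Cis_Stat6_DKO replicate 1 or 2, 802 and 397 genes had an unadjusted p under 0.05. Of the lists, 11, 11 and 10 passed camera as reported. With an estimated correlation 0, 0 and 0 passed and 3, 3 and 3 had an unadjusted p under 0.05, and with fry 0, 0 and 0 passed and 9, 9 and 4 had an unadjusted p under 0.05.

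The following values, none of them of a gene that was called, changed sign. Stat6 in Cis_KO against WT (0.08 as reported) was at -0.014 with library size only, -0.035 with FPKM and a pseudocount of 1 with or without a filter, -0.036 with a pseudocount of 0.1, and -0.07 to 0.204 over the left-out libraries, negative without Cis_KO replicate 1. Without Cis_KO replicate 2, Alas2, Hba-a1 and Cd79a turned to -2.803, -3.552 and -5.806 in Cis_KO against WT, where the highest values without another library were 7.006, 7.907 and 12.49. In Cis_Stat6_DKO against Cis_KO, Alas2 and Hba-a1 turned to 2.943 and 3.513 without that library, and the lowest values were -6.878 and -9.2. The B cell median in Cis_KO against WT ranged from -0.812 without that library to 5.708. The erythroid median ranged from -3.501 without it to 7.4, and in Cis_Stat6_DKO against Cis_KO from -8.423 to 3.496 without it. The median of the IL-4 and STAT6-induced list in Cis_Stat6_DKO against WT (0.263 as reported) was -0.03 without Cis_Stat6_DKO replicate 1. Cish in Cis_Stat6_DKO against Cis_KO ranged from -1.187 to 0.349, the latter without Cis_Stat6_DKO replicate 1. Of 147 gene results named or followed here, 63 were called. Ccn3 in Cis_KO against WT and in Cis_Stat6_DKO against Cis_KO, and Cxcl2 in the latter, were called under each of the 21 alternatives, with adjusted p of at most 0.0362, 0.0402 and 0.0485. No called gene result changed direction under any of them. Depth limits the genes at or near 0 counts, whose folds are bounds or wide ratios.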

Other observations

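The tests in this section were added after patterns had been seen in the results. For antioxidant genes and for the pseudogenes of Rpl29, the prediction was written before the values of the test were seen. For Cis_KO replicate 2, classical activation genes and called genes near Cish, it was written after.

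The antioxidant genes Hmox1 and Srxn1 fell with CIS loss. Hmox1, which breaks down haem, fell by 2.22 ± 0.22 (log2, SE, n = 2 per group) in Cis_KO against WT, and Srxn1, which repairs oxidised peroxiredoxins, by 1.74 ± 0.22, with adjusted p of 0.0268 and 0.0494 in edgeR. With Slc7a11 they belonged to the leading annotation term among lower genes, response to oxidative stress, which missed the threshold (adjusted p 0.138). A candidate explanation is a lower programme of NRF2, the transcription factor of the antioxidant response. It was tested on 25 further NRF2 target genes whose values had not been looked at. Their median log2 fold change was -0.926 in Cis_KO against WT, 22 were negative, 15 had an unadjusted p under 0.05 and 0 were called by edgeR, with a camera p of 9.28e-12 and a p of 0.00958 with an estimated correlation. Osgin1 was at -2.46 ± 0.42, Txnrd1 at -1.50 ± 0.27, Gclm at -1.38 ± 0.23 and Gsr at -1.27 ± 0.29. In Cis_Stat6_DKO against Cis_KO the median was 0.926 (camera p 1.84e-09, p of 0.0144 with an estimated correlation), and in Cis_Stat6_DKO against WT it was -0.03 (camera p 0.921). The medians relative to WT were -0.79 and -0.98 in the Cis_KO libraries and -0.03 and 0 in the Cis_Stat6_DKO libraries, so the shift did not rest on the deviant library. These values are consistent with lower NRF2 activity in cells without CIS, as a hypothesis. The mRNA of the NRF2 gene, Nfe2l2, was at -0.70 ± 0.20 in Cis_KO against WT and at 0.84 ± 0.20 in Cis_Stat6_DKO against Cis_KO, neither called (adjusted p 0.373 and 0.145). NRF2 protein and its activity were not measured, and a shared cause upstream of both NRF2 targets and inflammatory genes was not tested.

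Cis_KO replicate 2 combined blood cell genes with missing genes. Of the erythroid, neutrophil and B cell lists, 20 members were over 4-fold higher than in Cis_KO replicate 1 at 5 CPM or more, and the medians of the lists differed by 10.87, 2.53 and 5.18, which is consistent with blood cells in that lavage. In the same library 479 genes had 0 counts although every other library predicted at least 10, against 6 to 44 genes in the others. Admixed cells dilute transcripts but do not remove them, and 249 of these genes would keep at least 10 expected counts at a dilution by 50%, which argues against admixture as the cause of the missing genes. A small number of RNA molecules at the start of the library may account for these, and no biological explanation was tested.

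The median of the classical activation list lay below WT in both Cis_KO libraries and above WT in both Cis_Stat6_DKO libraries. Without Cis_KO replicate 2 the median of the list in Cis_KO against WT was -1.009, which argues against that library as the cause of the fall. Fewer neutrophils in Cis_KO and an effect of CIS loss on macrophages cannot be told apart as the cause of the fall: the neutrophil list was at -0.17 relative to WT in replicate 1, and its 1.69 in replicate 2 comes with the blood cell genes of that library, which leaves 1 library. In replicate 1 S100a8 stood at 11 CPM against 16.6 and 16.6 in WT, and S100a9 at 0.438 against 1.35 and 1.24, while Csf3r was at -0.90 ± 0.18 in Cis_KO against WT (adjusted p 0.181) and at -0.95 ± 0.18 in Cis_Stat6_DKO against WT. In Cis_Stat6_DKO the neutrophil list was at least 0.95 above WT in both libraries, so more neutrophils may contribute to the rise above WT there. This stays open beside an effect of the genotype on macrophages: Il1b stood at 4.5 CPM in Cis_KO replicate 2, whose neutrophil median was 1.69, and at 84.7 and 64.5 in Cis_Stat6_DKO, but 1 library decides nothing.

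Rpl29 fell in both mutants, and the labels name no reason for it. The summed CPM of Rpl29 and its 3 annotated pseudogenes differed by -5.72 (log2) between Cis_KO and WT, which argues against reads moving among these as the cause. Reads counted for unnamed copies were not covered. Rpl29 lies 864 kb from Cish on chromosome 9 (106429454 to 106431568, mm10), so sequence of another mouse strain carried along with the targeted allele could lower its counts. Apart from Rpl29, whose fall prompted the test, 2 genes were called within 20 Mb of Cish in Cis_KO against WT (Alas1 and 6430571L13Rik) where 1.03 were to be reached by chance (one-sided hypergeometric p of 0.277). In Cis_Stat6_DKO against WT, Rpl29 was called there and neither Alas1 (-0.99 ± 0.19, adjusted p 0.213) nor 6430571L13Rik was. Of the 9 genes called in the same direction in both mutants, Rpl29 alone lay in this window, and the cause for the others was not tested. With so few called genes, carried sequence and an effect of CIS loss on Rpl29 cannot be told apart.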
